A study of Mus musculus with 3143 samples.

How the data were processed

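Single cells of the glomerular fraction of adult mouse kidney were measured by Smart-seq2, which reads full-length polyadenylated RNA from 1 sorted cell per well and carries no molecular identifiers. Per the labels, all mice were C57BL/6, the tissue was dissociated with enzymes, and cells positive for a viability dye were sorted into plates. The deposited table gives, per the labels' processing notes, counts: whole numbers of reads for 46517 gene names in 3143 cells, with no normalization. The submitters' processing notes name TopHat2 2.1.1, SAMtools 0.1.18, featureCounts and Subread 1.4.6-p5 and the mouse build GRCm38 (mm10). The annotation, the strand setting, the handling of duplicate reads and any removal of cells are not given in the sources used here. No gene exceeded 3974 reads in a cell.

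Each cell is 1 sample in the labels and carries a plate number and a treatment, IgAN or Control. The labels name no animal, so each group was treated as 1 sample, no test was run between groups, and no p-value is given. Each of the 10 plates held cells of 1 group only, so plate and group cannot be told apart, and the spread between plates of a group is given in place of a replicate error. Intervals are exact, at 95%: binomial (Clopper-Pearson) for shares and Poisson for summed reads. They cover counting error only, because reads without molecular identifiers are not independent molecules. Where a group held 0 reads, a fold is a lower bound against 3 counts over the group.

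Cells needed at least 10000 reads in genes and 500 genes, which every cell had. The total was 816735155 reads, with 50365 to 1135415 reads per cell and a median of 234207. Genes with a read in at least 5 cells were scaled to 100000 reads per cell, log transformed and reduced to 2000 variable genes and 30 principal components. A graph of 15 neighbours gave 23 Leiden clusters at resolution 1. A cluster took the class whose markers had the highest mean log2 fold against all other cells (10 CPM added), among classes with at least 3 markers in 25% of its cells. It stayed unnamed when its 10 leading genes held more markers of another class, or 3 or more cell cycle genes. Markers came from 13 classes, and each class is called by its name with "like", because it rests on RNA alone.

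For each class, reads were summed over the cells of a group and scaled to CPM, counts per 1e6 reads. The log2 difference is IgAN minus Control with 1 CPM added. A gene was measured when it had at least 10 CPM and was found in at least 10% of the cells of the class in 1 group. It met the size rule when the log2 difference was at least 1 in either direction and every plate of a group, with at least 10 cells of the class, lay above every plate of the other. Podocyte-, mesangial- and endothelial-like cells were the main classes. Other classes were compared when at least 3 plates of each group held 10 cells. Of 28 gene lists fixed beforehand, only some are described, and not for every class. Each is given as the median log2 of its measured members, and lists of the main classes also with a percentile among 10000 random lists drawn from 20 bins of mean expression. Markers of other classes were summed in each class to measure carried-over RNA.

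The classes, markers, lists, size rule and named-gene rule were fixed before the data were examined. Named genes in each main class were the 12 largest differences in each direction among genes meeting the size rule, without markers of another class and unnamed gene models. List members meeting the size rule and the 4 most abundant members of a described list were also named. Some genes that this rule names are not described here. Genes named for the other classes followed the same order but were picked after the data were seen. Positions are GRCm38 coordinates of GENCODE vM21, matched by name for 42052 of the 46517 names; the match to the annotation used by the submitters is unknown. Nuclear copies of mitochondrial genes were found with BLAST+ 2.17.0 at an identity of at least 80%.

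The size rule was tested on simulated data, with the median plate spread of the class for every gene and plates that varied independently. Genes with no difference may therefore meet the rule more often in the data than in the simulation. Alternatives covered the cell filter, resolution, variable genes, scaling, filters, pseudocount, cells that carry markers of 2 classes, the fold limit and leaving out each plate. Fewer plates must lie apart when 1 with at least 10 cells of the class is left out, so the size rule is then easier to meet. Others were chosen after seeing the data: equal weight for plates, plates of at least 2 cells, subsets of clusters, and leaving out the 41 cells on the other group's side of a Gm13340 share of 30%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.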

Results

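The study compared kidney glomerular cells of mice labelled IgAN, for IgA nephropathy, a disease in which IgA collects in the mesangium, with cells of Control mice, to describe injury of the glomerulus cell by cell. IgAN gave 1798 cells on plates 313, 315, 316, 318, 322 and 325, and Control gave 1345 cells on plates 314, 317, 321 and 326. The median depth was 231222 reads per cell in IgAN and 241543 in Control. Plate 322 was the deepest, at a median of 396718 reads, and plate 325 the shallowest, at 177508. A cell held a median of 4683 genes, and 1.42% of its reads lay in the mitochondrial genome. The labels name no replicate animals, so each group was treated as 1 sample, and differences are set against the spread between plates.

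The first comparison asks which cell types each group yielded. Podocyte-like cells, the epithelial cells that hold the slit diaphragm, made up 39 of 1798 IgAN cells (2.17%, 95% interval 1.55 to 2.95) and 146 of 1345 Control cells (10.9%, 9.24 to 12.6). The share was 5.00 times as high in Control, and the plates did not overlap: 0.683% to 4.08% in IgAN and 8.11% to 13.2% in Control. B or plasma cell-like cells showed the same order, with 26 cells (1.45%, 0.947 to 2.11) in IgAN and 117 (8.70%, 7.25 to 10.3) in Control. Mesangial-like cells, the contractile cells between the capillaries, were 6.51% of IgAN cells (117 cells, 5.41 to 7.75) and 3.79% of Control cells (51 cells, 2.84 to 4.96). Endothelial-like cells, which line the capillaries, were 55.5% of IgAN cells (997 cells, 53.1 to 57.8) and 45.7% of Control cells (614 cells, 43.0 to 48.4).

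Plates of the groups overlapped for every class but podocyte- and B or plasma cell-like cells, with mesangial-like cells at 3.79% to 8.55% in IgAN and 1.34% to 4.80% in Control and endothelial-like cells at 40.6% to 65.2% and 29.9% to 51.8%. Macrophage or dendritic-like cells were 10.6% of IgAN and 7.66% of Control cells, and T or NK cell-like cells 5.17% and 9.52%. Proximal tubule-like cells were 8.06% and 6.32%, and distal tubule or collecting duct-like cells 4.00% and 3.42%. Parietal epithelial-like cells, which line Bowman's capsule, were 2.73% and 1.78%, smooth muscle or renin cell-like cells 1.17% and 0.818%, and neutrophil-like cells 0.445% and 0.892%. Among cells of the 5 glomerular classes alone, podocyte-like cells were 3.19% of 1223 in IgAN and 17.3% of 846 in Control, and endothelial-like cells were 81.5% and 72.6%. All shares depend on the dissociation and the dye sort. With cells left out that carried markers of 2 classes, mesangial-like cells were 0.129% of IgAN and 0.555% of Control cells, because 115 of 117 and 45 of 51 of them carried endothelial or podocyte markers as well.

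**Figure D1:**
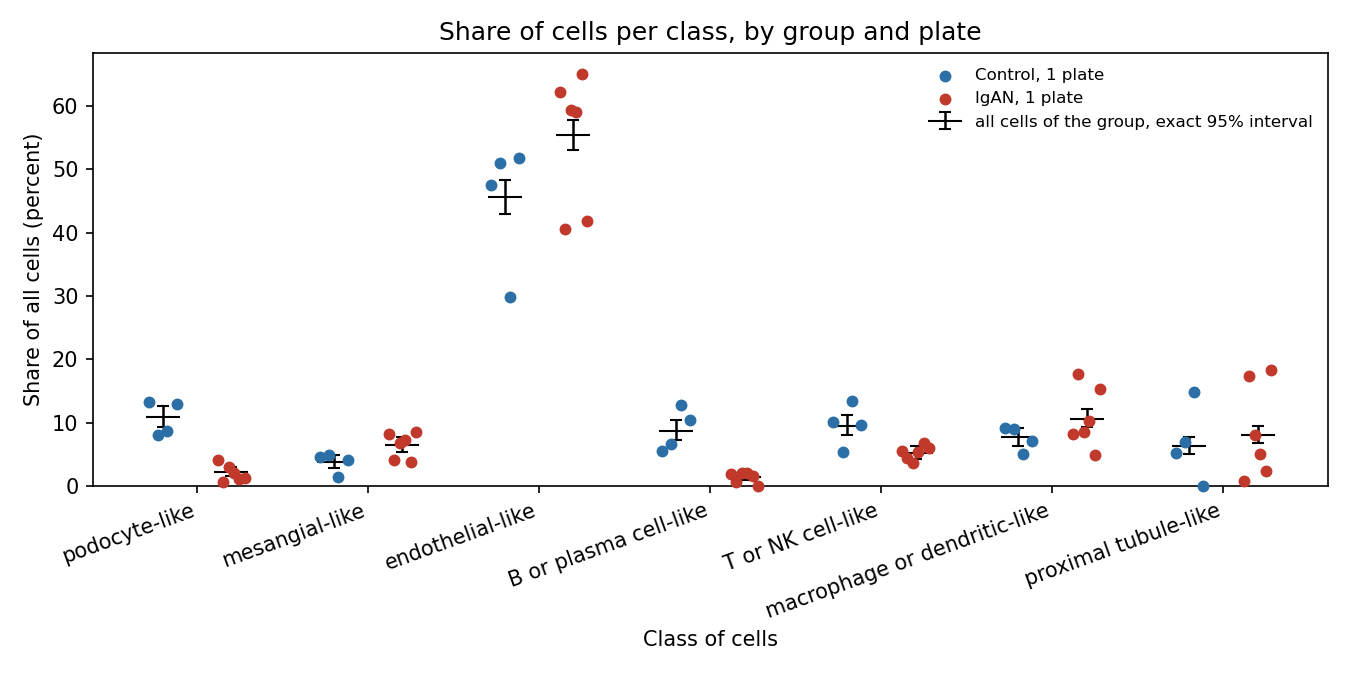
Share of all cells in each class (percent, linear axis), with 1 point per plate and a bar with its exact 95% interval for all cells of a group. The IgAN plates lie between 0.683% and 4.08% for podocyte-like cells, below the Control plates at 8.11% to 13.2%.

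The next comparison asks what differed inside endothelial-like cells. Genes of the interferon response, MHC class I presentation, and NF-kB and chemokines were higher in IgAN. All 25 measured interferon genes had positive differences, with a median log2 of 0.58, and the IgAN plates (0.30 to 0.96) lay above the Control plates (-0.15 to 0.07). Of these genes, 5 met the size rule: Isg15, a ubiquitin-like modifier (68.7 CPM, 67.7 to 69.7, against 29.3, 28.5 to 30.1), Usp18, which removes it (97.1 against 41.1), Rsad2, an antiviral enzyme (255 against 122), Gbp3 (84.0 against 31.9) and Oas1a (87.5 against 38.0), which has close paralogs. All 15 genes of MHC class I presentation were positive, with a median of 0.69. The proteasome subunit Psmb9 (165 against 77.2 CPM, log2 1.09) met the rule, and the MHC light chain B2m was at 2434 against 1549 CPM.

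All 17 measured genes of NF-kB and chemokines were positive too, with a median of 0.63 and IgAN plates at 0.38 to 0.75 against -0.20 to 0.07. The leukocyte adhesion receptor Icam1 (chromosome 9, 21015985 to 21028817) was at 351 CPM (349 to 354) in IgAN and 146 (144 to 148) in Control. The chemokine Cxcl16 was at 76.4 and 23.2 CPM, log2 1.68, and the chemokine Cx3cl1 at 714 and 392, log2 0.86. These 3 lists lay at percentile 100 of random lists, though 5 of 30 simulated lists with no difference lay outside the middle 95% in this class. In the complement list (median 0.41, but 0.01 with a 50 CPM filter and 0.27 without plate 317) Cd55, an inhibitor of complement on the cell surface, met the rule at 90.9 and 20.9 CPM, log2 2.07. Oxidative phosphorylation genes had a small positive median, 0.18, with overlapping plates. It was 0.26 without plate 313, 0.28 without 316 and 0.05 without 322. The percentiles were 99.6 for complement and 99.97 for oxidative phosphorylation.

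In the same cells 77 of 9684 measured genes were higher in IgAN by the size rule and 72 were lower. The largest positive differences among named genes were in Ifi44l (61.1 against 4.94 CPM, log2 3.39, and 5.96 without plate 317), the sodium-potassium-chloride cotransporter Slc12a2 (2.84), the growth factor Igf2 (2.80), Btnl9 (2.76), the kinase Dapk2 (2.50), the nucleic acid sensor Zbp1 (2.33) and Flrt2 (2.20). H2-Q6 (3.39) and H2-Q7 (2.43), MHC class I genes of near-identical sequence, are uncertain, as are Olfr1396 (2.75) and the repeat of its name (2.78). The clotting factor F8 was higher as well (log2 1.12). The largest negative differences among named genes were in Syt15 (-3.68), the riboflavin transporter Slc52a3 (-3.66), Tmem14c (-3.52), Pole, a DNA polymerase subunit (-3.47), Trim12a (-3.21, a gene with a close paralog), Sema3b (-2.74), Gsn, which severs actin filaments (38.4 against 231 CPM, -2.56), Fam174b (-2.54), Smim3 (-2.54), the gap junction protein Gja5 (36.8 against 208 CPM, -2.46), Pde3a (-2.16) and Ralb (-2.14). Tgfb2 was lower at -1.42, and the anticoagulant receptor Thbd was at 392 and 639 CPM, -0.71.

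The angiogenic list had a median of -0.21, with the receptors Tie1 at -0.44 and Tek at -0.24, and overlapping plates, and was at -0.14 without plate 326. Adhesion and junction genes were at -0.17. The slit diaphragm list was at -0.36, and at -0.23 without plate 317. The basement membrane list (-0.36, and -0.05 to -0.57 without 1 of plates 315, 316, 317 and 322) held Col4a3 (2.26 against 12.7 CPM), an abundant podocyte transcript that met the rule. The percentiles of these 4 lists were 0.870, 1.29, 0.0400 and 0.270. Podocyte markers summed to 552 CPM in endothelial-like cells of IgAN and 709 in Control. Of these cells 35 of 997 in IgAN and 105 of 614 in Control carried markers of 2 main classes. The class is made of several clusters, which differed by group and by plate. Clusters 0, 2 and 5 held 423, 220 and 205 of the 997 IgAN cells, cluster 1 held 421 of the 614 Control cells, and cluster 3 held 107 and 109. Plates 313 and 316 gave 188 and 164 cells of cluster 0, plates 315, 318 and 325 gave 52, 116 and 46 of cluster 2, and plate 322 gave 138 of cluster 5.

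Simulated genes with no difference met the rule 3 times in this class, and 30.0% of simulated 2-fold differences were found. The simulation held neither the clusters that plates share nor genes of wider spread, so these 3 do not measure how many genes chance gives here. The higher genes include 8 nuclear copies of mitochondrial genes, described below. Without cluster 3, led by Fbln5, the counts were 78 higher and 66 lower. Of the genes that met the rule with it, 62 higher and 47 lower ones met it again. Without plate 314 the counts were 117 higher and 115 lower, and scaling by the median of ratios gave 64 and 93, a higher share of 40.8% in place of 51.7%.

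**Figure D2:**
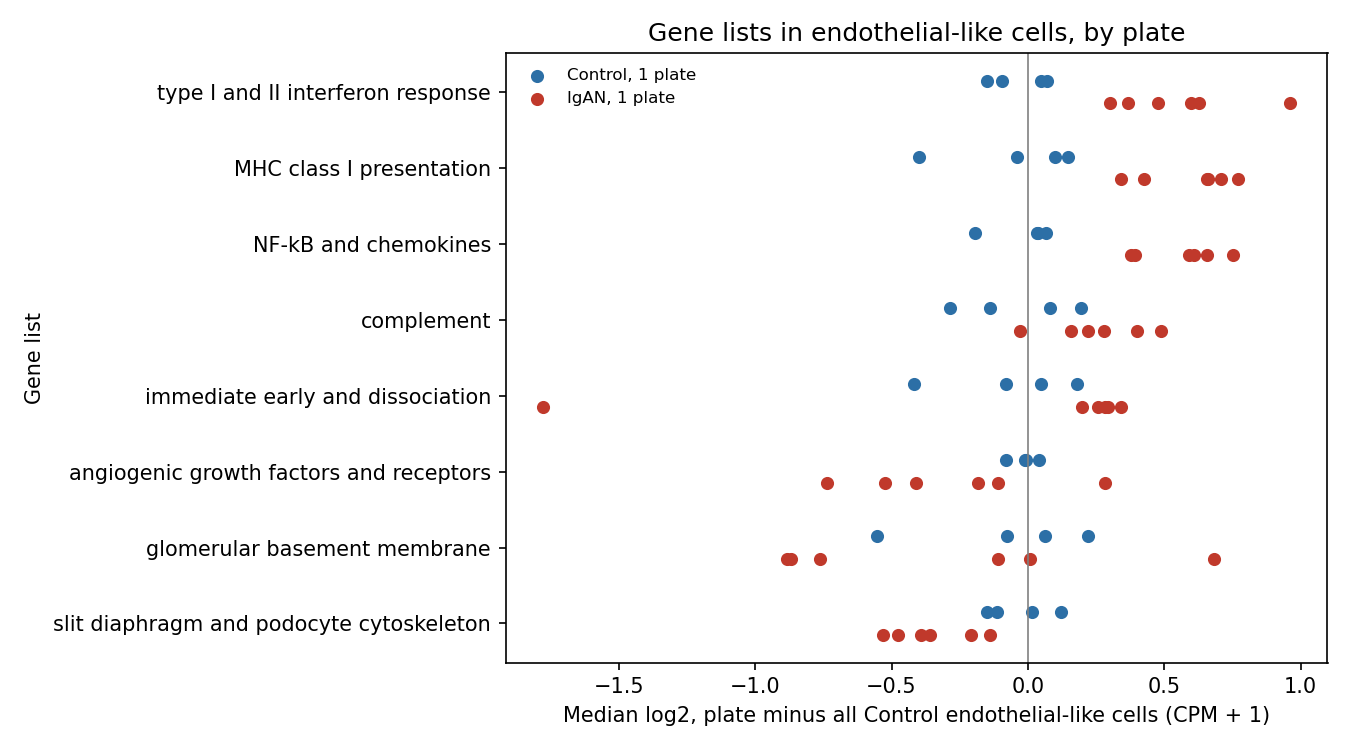
Median log2 of the measured genes of 8 lists in endothelial-like cells, each plate against all Control endothelial-like cells (CPM plus 1), with 1 point per plate. The IgAN plates lie at 0.30 to 0.96 for the interferon response, above the Control plates at -0.15 to 0.07.

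The comparison of mesangial-like cells asks how the cells at the site of IgA deposition differed. Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), was at 136 CPM (132 to 141) in IgAN and 0.0763 (0.00193 to 0.425) in Control, 3691 reads against 1, log2 6.99. The ratio was 1785, with a counting interval of 8.32 to 16.11 in log2. Spp1, the matrix phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), was at 165 and 2.06 CPM, log2 5.76. Fn1, the matrix protein fibronectin, was at 43.8 and 1.14 CPM, log2 4.39. Ankrd1, a nuclear cofactor of stretched muscle, had 1637 reads in IgAN and 0 in Control, at least 264-fold higher, and Lcn2, which binds bacterial siderophores, 890 and 0, at least 143-fold, with most from plate 315, without which its log2 was 0.95 in place of 5.08. These reads came from few cells: Ptgs2 was found in 30.8% of IgAN cells, Ankrd1 in 21.4% and Lcn2 in 13.7%.

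Genes of MHC class I presentation were all positive in mesangial-like cells, 15 of 15, with a median log2 of 0.53 and plates at 0.20 to 0.87 in IgAN and -0.22 to 0.06 in Control, and the median was 0.89 without plate 314. B2m was at 1549 and 812 CPM and H2-K1 at 862 and 491. Genes of the MHC class I and interferon lists were also higher in endothelial-like cells of IgAN, whose markers most mesangial-like cells carried. How much of these differences carried-over endothelial RNA makes up was not tested. NF-kB and chemokines (median 0.92, 15 of 19 positive), endothelial activation (0.77), angiogenic factors (0.62) and TGF-beta and PDGF signalling (0.47) were also positive, with overlapping plates in each. The last was at -0.11 with a 50 CPM filter, 0.10 without plate 325, 0.28 without 326 and 0.31 without 313. The interferon list had a median of 0.31 with 18 of 25 positive, and held Cxcl10 (log2 4.39), Oas1a (3.94) and Ifi44 (2.63, and 4.91 without plate 317). Against random lists MHC class I lay at percentile 99.8, NF-kB and chemokines at 99.99, endothelial activation at 99.8, angiogenic factors at 99.9, TGF-beta and PDGF signalling at 99.2 and interferon at 97.2, inside the middle 95%. The interferon median was 0.03 as a mean of cell CPM, 0.07 without plate 315, 0.13 without 326, 0.21 without 314 and 0.51 without 317. Other list members that were higher were Tagln, an actin-binding protein of smooth muscle (110 against 10.3 CPM, 3.29), Tgfb3 (2.28, and 4.93 without plate 321), H2-Q7 (2.22) and the lymphatic growth factor Vegfc (2.16).

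The matrix list as a whole was near 0, with a median of -0.08 (percentile 35.6): Sparc was at -0.15, Bgn at -0.11 and Col4a1 at -0.25, while Col5a2 was lower (53.5 against 304 CPM, -2.49). The contractile list was at 0.14 (percentile 88.0), or -0.01 without plate 318, with the filament protein Des lower at 588 against 1242 CPM, -1.08. The prostaglandin E receptor Ptger4 (-1.28), the transcription factor Wt1 (-1.23, and -0.78 without plate 317), Jam3 (-1.35) and the replication factor Mcm3 (-2.65) were lower too. Among the largest negative differences were St6galnac2 (10.9 against 273 CPM, -4.52), the potassium channel subunits Kcnd3 (325 reads in Control against 2, a ratio of 336, -6.53 to -11.44 in log2) and Abcc9 (-3.79), the neuropeptide Y receptor Npy1r (-3.76), Uhrf1 (181 against 2, 187, -5.67 to -10.60), BC018473 (355 against 2, 367, -6.66 to -11.57), Lrrc27 (-4.41), Cisd3 (-3.90), Cep170b (-3.84), Trim12a (-3.81), Tmem14c (-3.59) and Zfp804a (-3.56, and -5.44 without plate 313). With 1 CPM added Uhrf1 was at -3.79, and at -2.36 without plate 314. On the positive side stood Cep192 (at least 221-fold), Naprt (at least 138-fold), Lins (at least 129-fold), the scavenger receptor Stab2 (5.36, and 9.03 without plate 317), Ptgdr2 (5.20), the DNA damage kinase Atm (942 reads against 1, a ratio of 456, 6.35 to 14.14 in log2), Spint2 (4.92) and Slc36a4 (4.84).

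By the size rule 132 of 10210 genes were higher and 151 lower in mesangial-like cells, and the counts rest on few Control cells. Simulated genes with no difference met the rule 196 times, and 12.0% of 2-fold differences were found. Without plate 314 the counts were 368 and 357, without 317 they were 313 and 416, without 326 they were 290 and 366, and without 313 the higher count was 204. Endothelial markers in these cells were at 28.4% of their level in endothelial-like cells in IgAN and 22.4% in Control. Markers of proximal tubule (201 against 49.3 CPM), distal tubule or collecting duct (112 against 44.2), parietal epithelial (466 against 198) and podocyte-like cells (907 against 519) were higher in IgAN mesangial-like cells as well.

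The comparison of podocyte-like cells asks what differed inside the podocyte-like cells of each group. Immediate early genes, which dissociation also induces, were lower in IgAN. Of 18 measured, 9 were lower by the size rule and 2 higher, the median log2 was -1.82 (percentile 0), and the plates were at -2.26 to -1.69 in IgAN and -0.69 to 0.54 in Control. Fosb was at 9.50 CPM (7.74 to 11.5) in IgAN and 156 in Control, log2 -3.90, Ier2 at 37.4 and 397, -3.37, and Egr1 at 115 and 755, -2.71. Jun (-1.90), Fos (-1.74), Junb (-1.95), Zfp36 (-2.27), Dusp1 (-2.19) and Socs3 (-2.33) were lower too, while Nr4a1 (2121 against 852 CPM, 1.31) and Gadd45b (2.03) were higher. Without plate 314 Fosb was at -2.56 and Zfp36 at -1.41, and without plate 318 Egr1 was at -4.15.

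The slit diaphragm list had a median of 0.23 in podocyte-like cells, with 15 of 21 genes positive, none meeting the rule, and plates at 0.09 to 0.41 against -0.16 to 0.07. The median was 0.15 without plate 313 or 316 and 0.12 without 315. Podxl was at 4044 and 3447 CPM, log2 0.23, and Synpo at 3204 and 2730, 0.23. Basement membrane genes were at 0.25 (0.13 without plate 313, 0.14 without 317, 0.42 without 326, 0.01 as a mean of cell CPM), with Col4a3 at 0.07 and Col4a4 at 0.42. Podocyte transcription factors were at -0.38 (-0.61 without plate 315, -0.22 without 326), with Wt1 at 749 and 1188 CPM, -0.67. Contractile genes had a median of 2.19 (0.81 with no low filter, 1.13 without plate 318), and Tagln (117 against 14.0 CPM, 2.97), Acta2 (2.26, and 1.48 without plate 318), Cald1 (2.11) and Cnn2 (1.48) met the rule. Matrix genes were at 2.34, but at 0.17 with no low filter and 0.28 without plate 316, with the collagen cross-linking enzyme Lox (2.87, and 1.56 without plate 316) and Col4a2 (1.16, and 1.94 without plate 314) meeting the rule. Smooth muscle or renin cell markers in the same cells summed to 145 CPM in IgAN and 21.6 in Control. These markers include Tagln and Acta2, so the sum is no separate measure of carried-over RNA. MHC class II genes, 5 of 5, were lower, median -1.87 (-1.22 with a pseudocount of 5), and the markers of macrophage or dendritic-like cells, which carry them, were at 39.4 and 86.9 CPM. Of these lists the contractile and matrix genes lay at percentile 100 of random lists, the slit diaphragm at 98.2 and, inside the middle 95%, transcription factors at 2.93, basement membrane at 93.7 and MHC class II at 8.03.

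Oxidative phosphorylation (-0.24, Ndufv1 at -1.32), the unfolded protein response (-0.32, Ddit3 at -1.10), glycolysis (-0.14, the glucose transporter Slc2a1 at -1.57) and cytosolic ribosome genes (-0.14) had slightly negative medians. Without plate 316 oxidative phosphorylation was at -0.11 and Ddit3 at -0.71, without 318 Ddit3 was at -2.27, and without 313 the ribosome list was at -0.21 and glycolysis at 0.02. Glycolysis was also at -0.08 without plate 317, -0.05 without 321 and -0.01 without 316 or 322. The p53 list was at -0.18, but at 0.01 without plate 317 or with no low filter, and at -0.53 to -0.06 without 1 other plate. Oxidative phosphorylation lay at percentile 0.170 and the unfolded protein response at 0.480, while glycolysis (24.3), ribosome (7.42) and p53 genes (38.9) lay inside the middle 95%. The largest positive difference among named genes was in Parm1, a mucin-like membrane protein (chromosome 5, 91517615 to 91626894), at 377 CPM (366 to 389) in IgAN and 5.06 (4.42 to 5.77) in Control, log2 5.96. It was found in 51.3% and 6.16% of the cells. Others were Tshb (5.15), Pdlim4 (4.90, and 2.58 without plate 316), Tfcp2l1 (4.75), Ddah1, which breaks down an inhibitor of nitric oxide synthase (149 against 4.54 CPM, 4.75), Magi3 (4.68), Asrgl1 (4.52, and 2.84 without plate 322), the calcium channel Cacna1g (4.34), Plxna4 (4.30, but 0.21 without plate 316), Pdgfa (4.06) and Epb4.1l1 (4.05). Prss23 (4.16) overlaps an antisense gene and is uncertain. Among list members Clu, a chaperone also called clusterin (146 against 8.83 CPM, 3.90, and 2.11 without plate 316), F8 (2.93), Icam1 (1.99, but 0.79 without plate 318), Bag3 (1.56) and Itga1 (1.34, and 2.61 without plate 326) were higher.

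On the negative side Rab3il1, an exchange factor of Rab GTPases (chromosome 19, 10001669 to 10038380), had 1 read in IgAN and 4088 in Control, 0.0931 CPM (0.00236 to 0.519) against 92.8 (90.0 to 95.7), log2 -6.42. Control was 996 times IgAN, with a counting interval of -7.48 to -15.26 in log2. Ttc22 had 0 reads in IgAN and 1525 in Control, at least 124-fold lower, and the incretin receptor Glp1r 0 and 1149, at least 93.4-fold lower. The mitochondrial GTPase Rhot2 (-4.68) and Pycrl (-4.57) were lower. Other genes with 1 to 3 reads in IgAN were Hapln3 (Control 145 times IgAN, -5.63 to -9.46 in log2), Ppp1r37 (118, -5.34 to -9.16), Lrrc28 (157, -5.44 to -10.34), Ept1 (108, -5.21 to -9.04), Fndc4 (269.8, -5.59 to -13.38) and Mettl22 (269, -5.59 to -13.38). The list members Jam2 (-2.48), Hspa1a (-2.50, and -1.63 without plate 317), Klf2 (-1.40, but -0.72 without plate 314), Cx3cl1 (-1.22) and Ighm (-1.89) were lower as well. B or plasma cell markers in these cells were also lower, at 3.82 CPM in IgAN and 20.8 in Control.

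By the size rule 356 of 9547 genes were higher and 606 lower in podocyte-like cells. Only plates 313 and 316, with 15 and 10 cells, stand for IgAN: without 313 the counts were 694 and 1204, and without 316 they were 634 and 1183. With all plates of at least 2 cells, 18 genes were higher and 343 lower. Under that setting Jun, Fosb, Ier2 and Dusp1 met the rule as lower, and Parm1, Cnn2 and F8 as higher. With plates weighted equally the counts were 591 and 944, and simulated genes with no difference met the rule 127 times.

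Some nuclear copies of mitochondrial genes held more reads in IgAN cells of every class compared. Gm13340, a copy of mt-Co1, the gene of cytochrome c oxidase subunit 1, lies on chromosome 2, 22588103 to 22589647, with 97.6% identity. In endothelial-like cells it was at 909 CPM in IgAN and 11.7 in Control, while mt-Co1 was at 710 and 1375 CPM. The sum of both differed by 0.22 in log2, and that of mt-Nd2 and its copy by 0.15, or 0.66 in macrophage or dendritic-like cells. Of 18 such copies in the table, 8 were higher in each of the 6 classes, by 3.59 to 7.67 in log2, and the 7 copies nearly identical to their gene held at most 0.550 CPM in IgAN and 2.64 in Control in endothelial-like cells. The level of mt-Co1, which was lower in podocyte-like cells (-1.03), is not separable from its copy. Gm13340 took a median of 56.3% to 57.2% of the reads of the pair in the IgAN plates and 0% to 0.621% in the Control plates. In plate 317, labelled Control, 22 of 333 cells (6.61%, 4.19 to 9.83) had a share above 30%, 21 of them at 45.0% or more, and 5 others lay between 5% and 30%. In plates 318 and 322, labelled IgAN, 18 of 301 (5.98%, 3.58 to 9.29) and 1 cell had a share below 30%, and 8 of the 18 lay between 5% and 30%, between the groups. These 41 cells were kept in the group of their labels. Without them the counts were 83 and 74 in endothelial-like and 142 and 157 in mesangial-like cells. Gm13340 was singled out after its values were seen.

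**Figure D3:**
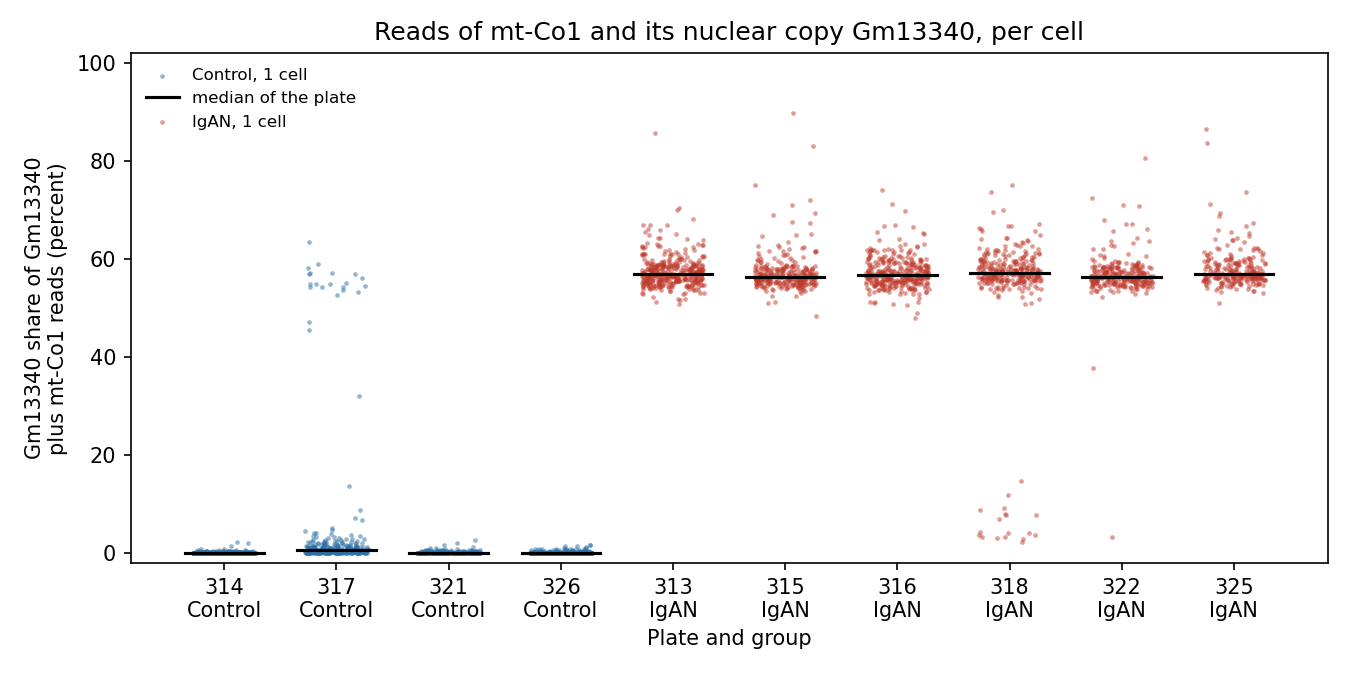
Share of Gm13340 among the reads of Gm13340 and mt-Co1 (percent, linear axis) in each cell, by plate, with a line at the median of the plate. The IgAN medians are 56.3% to 57.2% and the Control medians 0% to 0.621%, with 22 cells of plate 317 above 30% and 18 of plate 318 below it, 8 of them between 5% and 30%.

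Immune and tubule cells were compared next. In T or NK cell-like cells 44 of 9440 genes were higher and 118 lower. Ly6c2, a surface protein of memory T cells, was at 6.74 CPM in IgAN and 282 in Control, log2 -5.19. At least 1 read was found in 60.2% of IgAN and 58.6% of Control cells, with 148 and 8029 reads in all. So few reads per cell in IgAN cannot show whether the share of cells that express Ly6c2 differed. Reck (-5.14) and St6galnac2 (-4.80) were lower and Zfp568 (4.84), Ndrg2 (4.46) and the complement inhibitor Serping1 (3.56) higher. The last 3 varied between IgAN plates, Serping1 from 3.49 to 296 CPM, Zfp568 from 0.707 to 198 and Ndrg2 from 1.98 to 131. Markers of endothelial (1428 against 591 CPM), distal tubule or collecting duct (102 against 37.4) and smooth muscle or renin cell-like cells (45.3 against 15.6) were also higher in IgAN T or NK cell-like cells, and those of B or plasma cell-like cells lower (10.0 against 65.6). Cluster 10, led by T cell genes such as Cd3e and Cd8b1, held 83 of 128 Control cells and 32 of 93 IgAN cells, and cluster 11, led by Gzma and Ncr1 of cytotoxic cells, 45 and 61. In cluster 10 alone, with 1 IgAN plate, the counts were 1210 and 993, and in cluster 11 alone 267 and 492. Cells thinned to 1 depth gave 105 and 212 and the stricter cell filter 123 and 192, each with 4 IgAN plates in place of 6. Simulated genes with no difference met the rule 71 times. The rule is easier to meet with fewer plates, so counts rise by construction when a plate is left out. The higher count was 70 without 313, 80 without 314, 82 without 316, 75 without 325 and 89 without 326. The lower count was 216 without 313, 192 without 314, 180 without 316 and 212 without 317. It was 193 without 321, 223 without 322 and 187 without 326.

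In macrophage or dendritic-like cells 72 of 9885 genes were higher and 43 lower. The interferon list was positive, with a median of 0.85 and 22 of 25 members above 0, and MHC class II genes were at -0.92, with 7 of 8 below 0. The plates overlapped for both, at -0.01 to 0.88 in IgAN and -0.74 to 0.41 in Control for interferon and -2.15 to 0.26 and -0.17 to 0.19 for MHC class II, and only Ifi44 met the rule. BC018473 (0.102 against 104 CPM, log2 -6.57) and Cd177 (-4.12), a surface protein of neutrophils, were lower. Flrt2 (4.19), the apelin receptor Aplnr (4.28), F8 (3.94) and the NK receptor gene Klra9 (17.5 against 0 CPM), which has close paralogs, were higher. Endothelial markers in these cells summed to 2658 CPM in IgAN and 1282 in Control. Distal tubule or collecting duct (139 against 21.2), parietal epithelial (90.4 against 22.4) and smooth muscle or renin cell markers (54.4 against 14.5) were higher too. Podocyte (591 against 867), mesangial (271 against 345) and T or NK cell markers (68.6 against 97.3) were lower. Scaling by TMM shifted the median of all genes by -0.11 and by the median of ratios by -0.13. The higher share of the genes meeting the rule was then 46.8% and 45.1%, in place of 62.6%, and the lower counts were 66 and 67. Simulated genes with no difference met the rule 76 times. The higher count was 116 without plate 313, 185 without 314, 134 without 317 and 141 without 326. The lower count was 75 without 313, 100 without 314, 92 without 317, 105 without 321, 66 without 325 and 83 without 326.

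In proximal tubule-like cells 698 of 10403 genes were higher and 235 lower, and endothelial transcripts were among the higher. Endothelial markers summed to 5942 CPM in IgAN and 268 in Control, 29.8% and 1.33% of their level in endothelial-like cells. At least 3 such markers were found in 111 of 145 IgAN cells (76.6%, 68.8 to 83.2) and 33 of 85 Control cells (38.8%, 28.4 to 50.0). Macrophage or dendritic markers, 3 of which are MHC class II genes, were at 595 and 180 CPM, and the MHC class II list was at 1.98. The endothelial marker level was 6401 CPM in plate 315 and 10651 in plate 325, and 272 in plate 316. Vcam1, a leukocyte adhesion receptor, was at 125 and 0.320 CPM, log2 6.57. The chemokine Cxcl10 was at 100.2 and 0.213 CPM, 6.38, and Cxcl1 at 105 and 0.747, 5.93. Between Cxcl10 and Cxcl1 in size lay Gpihbp1 (6.25), Aplnr (5.99), Serpina3h (5.98) and Serpina3g (5.98). Cxcl1, Gpihbp1 and Serpina3g are also among the leading genes of endothelial cluster 2, and Serpina3h of cluster 0. Whether carried-over endothelial RNA accounts for the differences in these genes was not tested. Aoc1, an amine oxidase, was at 101 CPM in IgAN and 0 in Control. Scaling by TMM shifted the median of all genes by -0.30 and by the median of ratios by -0.32, the counts were then 465 and 491, and 462 and 510, and the higher share 48.6% and 47.5% in place of 74.8%. Simulated genes with no difference met the rule 409 times. The higher count was 1581 without plate 316, 1174 without 317, 1054 without 318 and 1289 without 321. The lower count was 424 without 314, 412 without 316, 432 without 317 and 521 without 321.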

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

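The test of podocyte markers outside the podocyte-like class was set before its result was seen, and all other tests of this part were chosen after the result was seen.

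Some nuclear copies of mitochondrial genes (8 of 18) held more reads in IgAN, a signal outside the named genes: Gm13340 was at 909 CPM in endothelial-like cells of IgAN and 11.7 in Control. Against transcription of Gm13340 alone, mt-Co1 was lower in all 6 classes, with a highest log2 of -0.90. Against plates processed differently, up to 22 cells of 1 plate (317) lay on the other group's side. In endothelial-like cells 24 other processed pseudogenes had a median of 0.0496, which argues against a different handling of processed pseudogenes at large. None of them copies a mitochondrial gene, and Gm13340 is an unprocessed pseudogene. A different handling of reads that mitochondrial genes share with their copies therefore stays open. A strain variant of the mitochondrial genome, which moves reads from gene to copy, stays open: the sums of mt-Co1 and mt-Nd2 with their copies, differed by -0.28 to 0.66 in log2 in the 6 classes. Transcription of the other copies also stays open: mt-Cytb, mt-Nd2, mt-Nd5 and mt-Nd6 were between -0.95 and 0.29. The test could not decide it for mt-Cytb, at 1850 CPM in endothelial-like IgAN cells, because its copy, at 36.0, held too few reads to move it. Nor could mt-Co2, which has a copy of 100% identity and held almost no reads in either group (0.0726 and 0.0701 CPM). Its copies Gm12155 and Gm13341 held 289 and 4.13 CPM. The sum with mt-Co2 differed by 4.17 to 6.38 in the 6 classes, which cannot decide it either. All mice carry the same strain label, and no genotype was tested.

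In plates 317, 318 and 322 there were 41 cells on the other group's side of a Gm13340 share of 30%, 22 labelled Control and 19 labelled IgAN. Of the 22 in plate 317, 95.5% lay at 45.0% or above, which argues against free RNA or reads from other wells as the source of these cells alone. The cut at 30% left out 5 more cells of the plate between 5% and 30%, for which this source stays open. In plate 318 the cut takes in that range. There this source stays open, because 55.6% of the 18 lay under 5% and 8 between 5% and 30%. Of the wells concerned in plate 318, 5.56% were concerned in plate 317, which argues against an exchange of wells between these plates. Whole cells of the other group, by mixing or a wrong label, may account for them: Tmem14c, lower in all 6 classes of IgAN, was lower by -4.29 in log2 (counting interval of the ratio -5.36 to -3.95) than in the other cells of plate 317, with reads in 40.9% against 53.4% of cells, and higher by 4.49 in the cells of plate 318, with reads in 50.0% against 14.8%. How such cells came to these plates was not tested.

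Podocyte-like cells were 2.17% of IgAN and 10.9% of Control cells. Podocytes placed in other classes account for little of it: cells outside the class with podocyte markers were 1.22% of IgAN and 0.669% of Control cells, a difference of 0.554 percentage points. Fewer podocytes in the glomeruli, and a lower yield of podocytes in dissociation and sorting, cannot be told apart. Markers of 2 main classes were found in 35 of 997 IgAN and 105 of 614 Control endothelial-like cells. Whether the second class was podocyte or mesangial was not separated. Podocyte markers in endothelial-like cells were 1.28 times as high in Control, between the ratio of 1 that a lower yield alone could give and the 5.00 that a loss could give. Other classes went both ways: the markers were at 907 CPM in IgAN against 519 in mesangial-like, 437 against 238 in proximal tubule-like, 296 against 167 in distal tubule or collecting duct-like and 440 against 376 in B or plasma cell-like cells, but at 160 against 271 in T or NK, 591 against 867 in macrophage or dendritic, 56.5 against 242 in neutrophil, 1632 against 1871 in parietal epithelial and 205 against 295 in smooth muscle or renin cell-like cells.

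Of 52 groups of plates examined, 7 held a plate far from the others, and chance gives about 1 in 20. Plate 322 stood apart in 3: unnamed cells were 11.0% of its cells (other IgAN plates 0% to 1.18%), and its immediate early genes had a median of -2.04 in mesangial-like (others -0.27 to 0.41) and -1.78 in endothelial-like cells (others 0.20 to 0.34). Plate 325 had a median of 1.97% mitochondrial reads (others 1.15 to 1.45), and plate 317 a median Gm13340 share of 0.621% (other Control plates 0). In mesangial-like cells MHC class I genes were at 0.20 in plate 316 (others 0.64 to 0.87), and in endothelial-like cells NF-kB and chemokine genes were at -0.20 in Control plate 314 (others 0.03 to 0.07). MHC class II genes were higher in IgAN in proximal tubule-like cells (1.98) and lower in podocyte-like cells (-1.87), 3.85 apart, a difference that was not tested. Macrophage or dendritic markers, 3 of 10 of them MHC class II genes, were at 595 and 180 CPM in proximal tubule-like cells and 39.4 and 86.9 in podocyte-like cells. Plate 322 alone held an unnamed cluster with endothelial markers led by Aqp2, Lzts1 and Pik3ca, 9.47% of its cells, with 25 cells in IgAN and 0 in Control.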

How the results depend on the processing

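The equal weight for plates, the plates of at least 2 cells, the T or NK clusters alone, the fit without the Fbln5 cluster and the fit without cells out of place were chosen after the data were seen. No paired analysis was possible because each plate held 1 group, no test was run, and the replicate numbers only name cells. Counts below are genes higher and lower in IgAN.

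The podocyte share stayed lower and the mesangial and endothelial shares higher in IgAN under each cell filter, resolution, number of variable genes and left-out plate, but with cells of 2 classes left out mesangial-like cells were 0.129% of IgAN and 0.555% of Control. The endothelial share of IgAN was then 62.3%, 58.8% with the stricter cell filter and 58.1% with 4000 variable genes. The main cell filter removes no cell. A 50 CPM filter, which measures fewer genes, gave 167 and 253 in podocyte-like, 40 and 35 in endothelial-like, 26 and 49 in T or NK, 28 and 25 in macrophage or dendritic-like cells, 65 higher in mesangial-like and 269 higher in proximal tubule-like cells. No low filter, which measures more, gave 129 and 120 in endothelial-like, 124 and 71 in macrophage or dendritic-like and 184 lower in T or NK cells. A 1.5-fold rule, wider by construction, gave 610 higher in podocyte-like, 124 and 136 in endothelial-like and 70 lower in macrophage or dendritic-like cells. TMM gave 66 lower in macrophage or dendritic-like and 465 and 491 in proximal tubule-like cells, and the median of ratios 67, and 462 and 510. In T or NK cells thinning gave 105 and 212, the stricter filter 123 and 192, cluster 10 alone 1210 and 993, and cluster 11 alone 267 and 492. Each of these left fewer plates of 10 cells, which makes the rule easier to meet by construction. In podocyte-like cells equal weight for plates gave 591 and 944. Plates of at least 2 cells gave 18 and 343, where more plates make the rule harder to meet by construction. Where no construction is named, the cause was not tested.

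With 1 plate left out, the lowest and highest counts were 373 to 694 higher and 606 to 1204 lower in podocyte-like, 135 to 368 and 161 to 416 in mesangial-like, 89 to 117 and 76 to 115 in endothelial-like, 55 to 89 and 155 to 223 in T or NK, 84 to 185 and 57 to 105 in macrophage or dendritic-like, and 702 to 1581 and 238 to 521 in proximal tubule-like cells. Where the plate left out held at least 10 cells of the class, fewer plates must lie apart, so these counts rise by construction. The lowest counts of podocyte-, mesangial- and proximal tubule-like cells came from plates 325, 321 and 313, which held fewer. There the plates that the rule compares did not change. The endothelial share ran from 53.7% to 58.3% in IgAN and 43.4% to 50.1% in Control. The p53 list of podocyte-like cells, at -0.18, turned to 0.0123 with no low filter and 0.0131 without plate 317 (lowest -0.53, without plate 316), and glycolysis, at -0.14, to 0.0223 without plate 313 (lowest -0.20, without plate 318). Why these lists changed was not tested.

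Over all alternatives, 80 gene counts moved by more than 1.5 times and 224 did not, and 82 list medians moved beyond their spread and 1803 did not. Of the values of single genes, 5114 moved beyond counting error and 5504 did not. None of those called by the size rule changed sign, which the rule makes likely beforehand, since it asks for a 2-fold difference with plates apart. Leaving out cells of 2 classes gives no mesangial genes, with 2 and 6 cells left. Depth limits the thinned comparison to 111000 reads per cell, which leaves out 212 IgAN and 101 Control cells. In simulated data 30.0%, 48.0% and 12.0% of simulated 2-fold differences were found in endothelial-, podocyte- and mesangial-like cells, and 100%, 88.0% and 46.0% of 4-fold differences.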

Other observations

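The values of Igha, Tmem14c and the other genes below were chosen after they were seen, and no explanation was tested for them.

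Igha, the heavy chain gene of IgA, had no read in any of 1798 IgAN cells (95% interval up to 0.205%), including 26 B or plasma cell-like cells. In Control it was found in 141 of 1345 cells (10.5%, 8.90 to 12.2), in 1.37% to 18.8% of the cells of a plate, with 12 of 117 B or plasma cell-like and 58 of 614 endothelial-like cells. Its companion Jchain, which links IgA and IgM chains, was found in 0.779% of IgAN and 7.96% of Control cells, with 1 cell in Control plate 326. Ighm, the heavy chain of IgM, was found in 26 of 26 and 116 of 117 B or plasma cell-like cells, at 4985 and 5471 CPM, and the light chain Igkc in all of them. In endothelial-like cells both were found less widely in IgAN, Ighm in 37.7% against 81.9% of cells and Igkc in 27.3% against 75.1%, and B or plasma cell markers in these cells summed to 6.46 CPM against 19.6. Across classes, Tmem14c was lower in IgAN by the size rule in all 6 classes compared (11.6 against 144 CPM in endothelial-like cells). Ralb, a small GTPase, was lower in the 5 classes that measured it (49.9 against 224 CPM in endothelial-like cells). The serine protease inhibitor genes Serpina3i and Serpina3h, close paralogs, were higher in 5 and 4 of 5 classes. Both are among the 10 leading genes of endothelial cluster 0. Serpina3h was at 404 CPM in endothelial-like IgAN cells and at 21.9 to 164 in the other classes that measured it. Endothelial markers were also higher in IgAN in each of these other classes, so carried-over RNA is not separable there.

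Within endothelial-like cells, cluster 2, led by the chemokine Cxcl1 and the leukocyte adhesion receptor Sele, held 220 IgAN and 5 Control cells, of which 52 were on plate 315, 116 on 318 and 46 on 325. Cluster 5, led by Gm20659 and Ppp1r16b, held 138 cells of plate 322 among 211, and cluster 3, led by the elastic fibre genes Fbln5 and Fbln2, held 107 IgAN and 109 Control cells. Macrophage or dendritic-like cells fell into 3 clusters: 115 IgAN and 48 Control cells in the one led by Treml4 and Cd300e, 52 and 45 in the one led by Fn1 and Ccr2, and 24 and 10 in the one led by the complement genes C1qc and C1qa. Oxidative phosphorylation genes were positive in these cells, with a median of 0.29, 28 of 38 members above 0 and overlapping plates. In T or NK cell-like cells all 25 cytosolic ribosome genes were negative, median -0.35, and proliferation genes were at -0.45, with overlapping plates for both and no proliferation gene meeting the size rule. An unnamed cluster led by Mki67 and Top2a, genes of dividing cells, held 15 IgAN and 8 Control cells.

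Endothelial markers in distal tubule or collecting duct-like cells summed to 6584 CPM in IgAN and 730 in Control, 33.0% and 3.62% of their level in endothelial-like cells. Xist, expressed from the inactive X chromosome, was found in 1795 of 1798 IgAN and 1338 of 1345 Control cells, and the Y-linked Ddx3y in 13 and 3 cells. The sex of the mice is not given in the sources used here.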
